A study of Mus musculus with 20 samples.

How the data were processed

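Total RNA of sorted bone marrow cells was amplified from 1 to 5 ng with a NuGEN whole-transcript kit, labelled with biotin and hybridized to single-channel gene arrays, per the labels' protocols. The 20 arrays fall into 6 groups, from 3 populations and 2 genotypes, with each array placed by its title. The labels do not say whether the replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. They also do not state whether or when Cre was induced, whether WT mice carried Cre, or on which days samples were taken.

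The deposited values are on a log2 scale, as their range of 1.77 to 13.2 shows. The submitters' processing notes name RMA, Partek 6.6 and limma without giving their roles or order. RMA corrects the background, normalizes arrays to each other by quantiles and summarizes probes into probe sets, so that a change shared by most transcripts is removed. Whether all 20 arrays were normalized together is not given in the sources used here. Array medians (4.76 to 4.91) and interquartile ranges (3.19 to 3.40) were close in all populations. No scanner files were analysed here, so detection above background was not assessed. The 20 columns were matched to samples by their names.

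Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation given with the values, 1814 had several and 16010 were unnamed here. Entrez identifiers of 23328 named probe sets were found in a RefSeq gene table (assembly GRCm38.p6), 193 were not, and 0 symbols changed. For each of 22180 genes the probe set with the highest mean over all arrays was kept, and genes with a mean at or above the 25th percentile of the single-gene probe sets (log2 3.86) were tested, which left 16638 genes. Several probe sets existed for 1082 genes.

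Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend), with 1 fit of all 20 arrays and a mean for each of the 6 groups, which leaves 14 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 16638 genes of a comparison, and a gene is called at an adjusted p under 0.05. Changes are Rptor minus WT, or WT GMP minus WT CMP, in log2 units with the standard error of the model. There were 7 comparisons: the genotype in each population, WT GMP against WT CMP, and 3 interactions, each the difference between the genotype changes of 2 populations. The shared estimate of the spread was fixed in the design, although the Lin⁻ + M-CSF arrays turned out to spread more than the others.

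Gene lists were written before the data were examined, 21 for pathways and 12 for cell types, including types that the gates could hold besides the intended one. They name 736 genes, of which 668 had a named probe set and 652 were tested. Each of the 33 lists was tested with limma's camera at its preset correlation between genes of 0.01, which compares the list's genes with all others, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated for each list was run beside it, and it held the calls of 0 lists in CMPs, 1 in GMPs, 3 in Lin⁻ + M-CSF cells and 3 between WT GMPs and WT CMPs, and of 0 in each interaction. The mean change of a list is given with a 95% interval over arrays, from the list's mean on each array and the spread pooled over the 6 groups.

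The genes named follow a rule set before the data were examined. For each genotype comparison and for WT GMP against WT CMP they are the 10 of largest change in each direction among called genes whose arrays do not overlap between the groups. For each interaction they are the 5 of largest change in each direction among called genes, and for each list described up to 4 members of smallest p. The rule also names 17 genes of the pathway and of myeloid fate, of which 15 had a tested probe set. These are given for the 3 genotype comparisons and otherwise where called, a limit set after the values had been seen. An immunoglobulin kappa variable segment among the 10 largest rises between WT GMPs and WT CMPs is not reported here. Predicted genes, unnamed transcripts, olfactory and vomeronasal receptors and small RNA genes without a standard name were counted but not named.

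The alternatives tried were no filter or a 50th percentile filter on dim genes, the mean of a gene's probe sets, every probe set on its own, each population or pair of populations fitted alone, the replicate number as a block, array weights, a trended and robust eBayes, repeated quantile normalization, arrays centred on their median, cyclic loess, a fold change of at least 1.5, an ordinary linear model, camera on ranks or with an estimated correlation, and each array left out in turn. Figures were drawn with Python and matplotlib.

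The test was checked on simulated data with the spread of the real arrays and 100 genes per size of change. Of genes changed by 0.5 log2 units, 37% were called in CMPs, 41% in GMPs and 57% in Lin⁻ + M-CSF cells, and of those changed by 1 log2 unit 97%, 98% and 100%. Unchanged genes made up 4.86%, 4.14% and 2.98% of the calls. A list shifted by -0.4 was called in each of these 3 comparisons with 0 other lists called. The simulated genes vary independently, unlike real ones. Every simulated array was given the same spread, whereas the real Lin⁻ + M-CSF arrays spread more. Far fewer genes were changed in the simulation than were called in the real data, and the Benjamini-Hochberg cut is stricter when fewer genes change. The shares above therefore do not show how the test fares with unequal spreads or with more changed genes.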

Results

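Gene expression was measured on 20 whole-transcript arrays in 3 bone marrow populations of female mice on a C57BL/6 background. Common myeloid progenitors (CMPs), which give rise to granulocytes, monocytes, erythroid cells and platelets, and granulocyte-macrophage progenitors (GMPs), which lie further along the granulocyte and monocyte path, were taken directly from the sort. Lineage-negative (Lin⁻) marrow cells, the immature fraction without markers of mature blood cells, were given macrophage colony-stimulating factor (M-CSF, 10 ng/ml) for 12 h in culture. Each population came from wild-type (WT) mice and from mice carrying CreER and floxed Rptor alleles (CreER-Rptor-flox/flox), called Rptor cells here. Rptor encodes Raptor, the scaffold protein of the growth-regulating kinase complex mTORC1. CMPs and GMPs had 3 arrays per genotype and the Lin⁻ + M-CSF cells had 4. The comparisons ask how the genotype relates to expression in each population. Each array correlated with the others of its group at 0.982 or higher, and array medians lay between 4.76 and 4.91 on the log2 scale. The residual spread of an array around its group mean was 0.120 to 0.156 in CMP, 0.109 to 0.168 in GMP and 0.171 to 0.236 in Lin⁻ + M-CSF arrays. The number of arrays limits the precision of the values below, which are log2 changes with the standard error (SE) of the limma fit.

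The Rptor probe set itself differed little between genotypes. Its log2 signal was 8.64 ± 0.11 (SD, n = 3) in WT CMPs and 8.34 ± 0.13 (SD, n = 3) in Rptor CMPs. In GMPs it was 9.28 ± 0.14 (SD, n = 3) in WT and 9.11 ± 0.23 (SD, n = 3) in Rptor cells, and in Lin⁻ + M-CSF cells 7.13 ± 0.17 (SD, n = 4) and 6.95 ± 0.09 (SD, n = 4). None of the 3 differences passed the limma test across genes (adjusted p = 0.163, 0.465 and 0.305). A two-sided exact permutation test of the Rptor values gave p = 0.1 in CMPs and 0.5 in GMPs, where 0.1 is the smallest value that 3 against 3 arrays allow, and 0.143 in Lin⁻ + M-CSF cells. Single Rptor arrays read 8.20, 8.37 and 8.45 in CMPs against 8.72, 8.51 and 8.68 in WT. In GMPs they read 9.25, 9.24 and 8.85 against 9.25, 9.17 and 9.44, and in Lin⁻ + M-CSF cells 6.92, 6.98, 7.06 and 6.83 against 7.05, 6.95, 7.34 and 7.17. Where the probes lie relative to the floxed part of the gene was not used here, and a probe set outside that part checks no label. Mtor, the kinase, and Rictor, the scaffold of the other mTOR complex, did not pass in any population. Mtor differed by -0.15, 0.00 and 0.16 and Rictor by 0.31, 0.04 and 0.10 in CMPs, GMPs and Lin⁻ + M-CSF cells.

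In CMPs, Rptor cells had lower levels of several monocyte and neutrophil transcripts and higher levels of erythroid transcripts. Csf1r, the receptor for M-CSF, fell by 1.51 ± 0.11 log2 units (adjusted p = 4.53e-09), and Irf8, a transcription factor of monocyte and dendritic cell formation, fell by 1.88 ± 0.18. Klf4 fell by 0.80 ± 0.15 and Spi1, which encodes PU.1, fell by 0.58 ± 0.12. Of the neutrophil granule genes, Ltf fell by 3.77 ± 0.27 and Camp fell by 3.70 ± 0.22. The interferon-inducible gene Ifi209 had the largest fall (-3.99 ± 0.22). The largest rise was that of Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes, at 4.33 ± 0.18 (8.84 ± 0.25 against 4.51 ± 0.35, SD, n = 3 each, the WT level lying below the array medians). Rhag, a red cell membrane protein, rose by 2.48 ± 0.38. The metallothionein Mt2 rose by 2.66 ± 0.23 and the fatty acid binding protein gene Fabp4 by 2.96 ± 0.34.

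The other genes of largest rise in CMPs were Clca3a1 (3.16), Rec8 (3.01), Bex4 (2.62), Ano1 (2.61), Rab4a (2.59) and Sapcd1 (2.38). The others of largest fall were Ms4a4c (-2.90), Hspa1a (-2.52), Ighm (-2.35), Ly6a2 (-2.35), Hk3 (-2.09), Itga1 (-2.02) and Abca9 (-2.00). These 20 genes had limma adjusted p of at most 0.0096. The heat shock gene Hspa1a read 4.81, 8.27 and 6.22 on the WT CMP arrays against 4.02, 3.71 and 3.99 on the Rptor CMP arrays, and its call was lost without WT CMP replicate 2 (0.0841), where it differed by -1.61. With the mean of its probe sets Ighm fell less, with a change of -0.91. In all, 1905 of 16638 genes passed at an adjusted p under 0.05, 1000 higher and 905 lower in Rptor CMPs. The balance turned with arrays centred on their median (905 higher and 1011 lower), with array weights (1503 and 1545), without WT CMP replicate 2 (660 and 838) and without Rptor CMP replicate 2 (595 and 634). The arrays of the 2 genotypes did not overlap for 5127 genes (30.8%, against 10% by chance), 1877 of them called. The count of called genes was 1229 without Rptor CMP replicate 2 and 3048 with array weights.

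Among the gene lists fixed beforehand, erythroid genes moved furthest upward in Rptor CMPs, with 15 of 22 tested members higher and 0 lower (18 and 1 adjusted over the list alone). Their mean change was 1.01 (95% interval 0.62 to 1.39), with camera adjusted p = 1.16e-14, adjusted p = 0.102 with an estimated correlation. Epor, the erythropoietin receptor, rose by 1.63 ± 0.22, the water channel Aqp1 by 1.64 ± 0.24, Add2 by 1.59 ± 0.23 and Sphk1 by 1.45 ± 0.17. Primary granule and granulocyte progenitor genes were lower, with 0 of 15 tested members higher and 9 lower (0 and 12 adjusted over the list alone) and camera adjusted p = 2.99e-11, adjusted p = 0.102 with an estimated correlation. Clec12a (-1.94 ± 0.10), the granulocyte transcription factor Cebpe (-1.76 ± 0.17) and the ficolin Fcnb (-1.84 ± 0.21) were among them. Secondary granule and mature neutrophil genes had 2 of 19 tested members higher and 8 lower (3 and 8 adjusted over the list alone) and camera adjusted p = 4.56e-06, adjusted p = 0.454 with an estimated correlation. Besides Ltf and Camp, Ngp (-1.86 ± 0.13) and S100a8 (-0.79 ± 0.11) were lower. Eosinophil genes had 0 of 7 tested members higher and 4 lower (0 and 5 adjusted over the list alone) and camera adjusted p = 0.00358, adjusted p = 0.411 with an estimated correlation, with Epx at -1.74 ± 0.39 and Prg2 at -1.36 ± 0.24.

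Monocyte and macrophage genes went both ways in Rptor CMPs, with 5 of 30 tested members higher and 10 lower (7 and 11 adjusted over the list alone). Besides Csf1r, Ms4a6c (-1.61 ± 0.12), Fn1 (-1.95 ± 0.17) and Ly6c2 (-1.17 ± 0.11) were lower. The list was called as lower (camera adjusted p = 0.0203, adjusted p = 0.454 with an estimated correlation). That call was lost on ranks (adjusted p = 0.663), with CMP arrays fitted alone (0.152), with the replicate number as a block (0.0667), and without Rptor CMP replicate 1 (0.0609) or Rptor CMP replicate 2 (0.0547). The mean change was -0.19, or -0.33 with the stricter filter on dim genes. Dendritic cell genes were higher, with 4 of 14 tested members higher and 0 lower (4 and 0 adjusted over the list alone) and camera adjusted p = 0.00155, adjusted p = 0.25 with an estimated correlation. The 4 members were the class II genes H2-Aa (1.77 ± 0.21), H2-Eb1 (1.77 ± 0.22) and H2-Ab1 (1.08 ± 0.19) and the transcription factor gene Zbtb46 (0.86 ± 0.13).

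Of the pathway lists, cholesterol synthesis was lower in Rptor CMPs, with 0 of 19 tested members higher and 8 lower (0 and 12 adjusted over the list alone). Its mean change was -0.37 (95% interval -0.54 to -0.20), with camera adjusted p = 4.32e-06, adjusted p = 0.218 with an estimated correlation. Fdps, an enzyme of isoprenoid synthesis, fell by 1.27 ± 0.12, Stard4 fell by 0.64 ± 0.12 and Srebf2, a transcription factor of the pathway, fell by 0.55 ± 0.11. Interferon-stimulated genes were lower, with 0 of 26 tested members higher and 9 lower (1 and 9 adjusted over the list alone) and camera adjusted p = 2.77e-06, adjusted p = 0.102 with an estimated correlation. Oasl2 (-1.46 ± 0.16) and Parp14 (-0.59 ± 0.10) were among them. Unfolded protein response genes were lower, with 1 of 17 tested members higher and 8 lower (1 and 10 adjusted over the list alone) and camera adjusted p = 2.75e-05, adjusted p = 0.165 with an estimated correlation. Sdf2l1 (-0.85 ± 0.14) and the chaperone gene Calr (-0.53 ± 0.10) were lower, and Ddit3, a transcription factor of that response, was higher (0.75 ± 0.14). Ribosome biogenesis and Myc targets were higher, with 4 of 34 tested members higher and 0 lower (5 and 0 adjusted over the list alone) and camera adjusted p = 0.000129, adjusted p = 0.468 with an estimated correlation, and so were cytosolic ribosomal proteins, with 2 of 30 tested members higher and 0 lower (2 and 0 adjusted over the list alone) and camera adjusted p = 0.00145, adjusted p = 0.165 with an estimated correlation. Nop14 rose by 0.47 ± 0.11 and Rpl3 by 0.53 ± 0.12, though with the mean of its probe sets Rpl3 differed by 0.24 without passing (0.193).

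The lysosome and autophagy list was higher in Rptor CMPs, with 7 of 31 tested members higher and 1 lower (10 and 1 adjusted over the list alone) and camera adjusted p = 0.00929, adjusted p = 0.411 with an estimated correlation. Besides Gpnmb, Ctsl (1.22 ± 0.14) and Fnip2 (1.31 ± 0.16) rose, and Hexa fell (-0.88 ± 0.10). Its call was lost without Gpnmb and Atp6v0d2 (adjusted p = 0.0912), on ranks (adjusted p = 0.0701) and with the stricter filter on dim genes (0.0547). The list of the TCA cycle and pyruvate dehydrogenase was higher, with 1 of 17 tested members higher and 0 lower (1 and 0 adjusted over the list alone) and camera adjusted p = 0.0185, adjusted p = 0.454 with an estimated correlation. Its call was lost with the stricter filter (0.0547) and without Rptor CMP replicate 2 (0.0543) or WT CMP replicate 2 (0.052). The other 20 lists had adjusted p from 0.0603 to 0.923. Among these, megakaryocyte and platelet genes had a mean change of 0.04 (95% interval -0.19 to 0.27) and stem and multipotent progenitor genes of -0.11 (95% interval -0.25 to 0.03). In CMPs 13 lists were called, and up to 15 in other splits of the same arrays, each of which keeps part of the genotype difference.

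**Figure D1:**
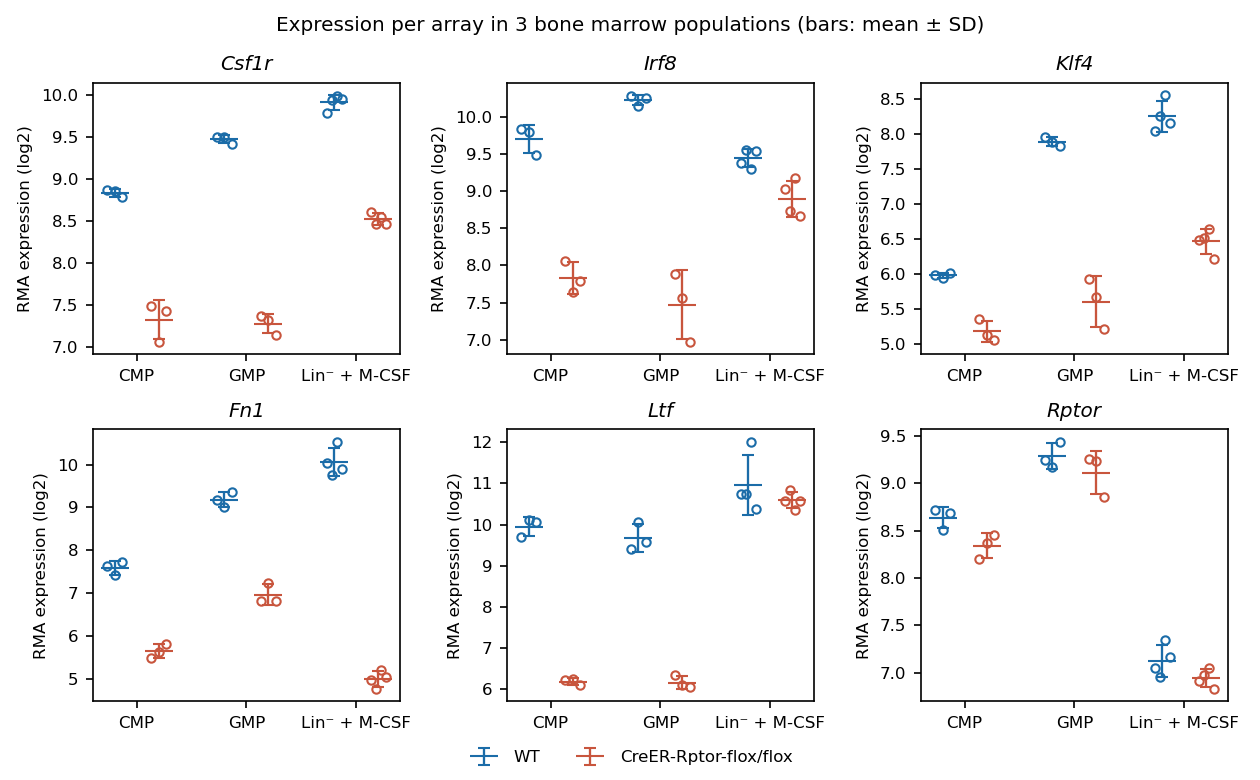
RMA expression (log2) of 6 genes on each of the 20 arrays, by population and genotype. Open circles are arrays, bars give the mean and SD of a group of 3 or 4, and Rptor arrays lie below all WT arrays of their population in Csf1r, Irf8, Klf4 and Fn1.

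In GMPs, Csf1r fell by 2.20 ± 0.11 in Rptor cells (adjusted p = 1.15e-11), Irf8 fell by 2.76 ± 0.18 and Klf4 fell by 2.28 ± 0.15. The fall was larger than in CMPs by the interaction test for Csf1r (-0.69, adjusted p = 0.0154, a call lost with the replicate number as a block (0.0581), with repeated quantile normalization (0.0537) and without Rptor CMP replicate 1 (0.0539)) and Klf4 (-1.49, adjusted p = 0.000375). The largest falls were those of Ifi209 (-4.26 ± 0.22), Ltf (-3.53 ± 0.27) and the eosinophil peroxidase gene Epx (-3.35 ± 0.39). Clec7a, a receptor for fungal glucans, fell by 2.54 ± 0.12 and the cytokine receptor gene Il31ra fell by 3.00 ± 0.22. Gpnmb had the largest rise, 4.16 ± 0.18, followed by Il1r2, a decoy receptor for interleukin-1, at 3.67 ± 0.35 and Svep1 at 3.60 ± 0.15 (1.83 with the mean of its probe sets).

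The other genes of largest rise in GMPs were C4b (2.91), Cd33 (2.86), Ambp (2.84), Cntnap1 (2.83), Il20ra (2.82), Lipg (2.74) and Gpc3 (2.66). The others of largest fall were Hspa1a (-3.15), Itga1 (-3.12), Camp (-2.97) and Ms4a4c (-2.93). The 20 genes of the rule had limma adjusted p of at most 0.00162. Hspa1a read 5.32, 8.60 and 6.81 on the WT GMP arrays against 3.80, 3.59 and 3.89 on the Rptor GMP arrays. In all, 1980 genes passed, 727 higher and 1253 lower in Rptor GMPs. The split was closer with arrays centred on their median (887 and 1070), with repeated quantile normalization (820 and 1043), with cyclic loess (877 and 1080) and with array weights (2459 and 2869). The arrays did not overlap for 5389 genes (32.4%, against 10% by chance), 1911 of them called. The count was 1183 without WT GMP replicate 2, 1256 without Rptor GMP replicate 2, and 5328 with array weights. Those weights were uneven, at 4.70 for Rptor GMP replicate 1 and 0.82 and 0.52 for the other Rptor GMP arrays.

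Cell cycle genes were lower in Rptor GMPs. G2 and mitosis genes had 0 of 22 tested members higher and 16 lower (0 and 20 adjusted over the list alone), with a mean change of -0.63 (95% interval -0.82 to -0.45) and camera adjusted p = 1.25e-17, adjusted p = 0.0921 with an estimated correlation. Kif23 fell by 1.38 ± 0.14, Nusap1 fell by 0.99 ± 0.11 and the mitotic kinase gene Aurkb fell by 0.75 ± 0.11. S phase and replication genes had 0 of 25 tested members higher and 5 lower (0 and 7 adjusted over the list alone) and camera adjusted p = 4.13e-05, adjusted p = 0.405 with an estimated correlation, with Tk1 at -0.58 ± 0.11 and Gins1 at -0.52 ± 0.11. Cholesterol synthesis genes were lower, with 0 of 19 tested members higher and 13 lower (0 and 15 adjusted over the list alone). Their mean change was -0.62 (95% interval -0.79 to -0.45), with camera adjusted p = 1.03e-12, adjusted p = 0.0722 with an estimated correlation. Sqle, squalene epoxidase, fell by 1.67 ± 0.17, Stard4 fell by 1.06 ± 0.12 and Mvd fell by 0.67 ± 0.10. Interferon-stimulated genes were lower, with 0 of 26 tested members higher and 11 lower (1 and 15 adjusted over the list alone), and this was the list in GMPs whose call held with an estimated correlation (camera adjusted p = 1.22e-08, adjusted p = 0.0421 with an estimated correlation). Oasl2 (-1.59 ± 0.16) and Usp18 (-1.18 ± 0.15) were among them.

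Among the other lists in GMPs, monocyte and macrophage genes went both ways, with 4 of 30 tested members higher and 11 lower (6 and 11 adjusted over the list alone) and camera adjusted p = 0.00192, adjusted p = 0.405 with an estimated correlation. The call was lost on ranks (adjusted p = 0.679) and with GMP arrays fitted alone (0.12). Fn1 fell by 2.22 ± 0.17. Erythroid genes were higher, with 7 of 22 tested members higher and 1 lower (9 and 1 adjusted over the list alone) and camera adjusted p = 6.67e-05, adjusted p = 0.49 with an estimated correlation, led by the carbonic anhydrase genes Car1 (2.60 ± 0.40) and Car2 (1.35 ± 0.21). The mean change was 0.58, and 0.37 without Rptor GMP replicate 2. Eosinophil genes were lower, with 0 of 7 tested members higher and 4 lower (0 and 4 adjusted over the list alone) and camera adjusted p = 0.00175, adjusted p = 0.405 with an estimated correlation, and Ear6 was at -1.66 ± 0.38. Dendritic cell genes were higher, with 2 of 14 tested members higher and 0 lower (3 and 0 adjusted over the list alone) and camera adjusted p = 0.0352, adjusted p = 0.49 with an estimated correlation, and H2-Aa rose by 1.59 ± 0.21. That call was lost on ranks (adjusted p = 0.0687), with array weights (0.0531), with repeated quantile normalization (0.0506) and without Rptor GMP replicate 2 (0.0839) or WT GMP replicate 1 (0.0958). Ribosome biogenesis and Myc targets were higher, with 4 of 34 tested members higher and 1 lower (10 and 1 adjusted over the list alone) and camera adjusted p = 0.00128, adjusted p = 0.639 with an estimated correlation, and so were cytosolic ribosomal proteins, with 2 of 30 tested members higher and 0 lower (2 and 0 adjusted over the list alone) and camera adjusted p = 0.017, adjusted p = 0.405 with an estimated correlation. The mean change of ribosome biogenesis and Myc targets was 0.175, with a 95% interval of -0.006 to 0.356 that holds 0. Rpl3 rose by 0.59 ± 0.12 and Ltv1 fell by 0.41 ± 0.09. The other 23 lists had adjusted p from 0.0602 to 0.988, among them primary granule genes with a mean change of 0.04 (95% interval -0.14 to 0.23).

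In Lin⁻ cells after 12 h of M-CSF, 3 of the 10 genes of largest fall in Rptor cells, Fn1, Msr1 and Fcgr1, belong to the monocyte and macrophage list. Fibronectin (Fn1) fell by 5.07 ± 0.15 (adjusted p = 5.17e-16), from 10.06 ± 0.34 (SD, n = 4) in WT to 4.99 ± 0.18 (SD, n = 4) in Rptor cells. The scavenger receptor Msr1 fell by 4.56 ± 0.18, the proteoglycan Vcan fell by 4.50 ± 0.11, the lectin receptor Clec4a1 fell by 4.34 ± 0.09 and the high-affinity IgG receptor Fcgr1 fell by 3.62 ± 0.16. Csf1r fell by 1.39 ± 0.09, Klf4 fell by 1.79 ± 0.13 and the lipid receptor Cd36 fell by 2.06 ± 0.33. Irf8 fell by 0.54 ± 0.16 (adjusted p = 0.0249), a call lost with array weights (0.0774), with an ordinary linear model (0.0553) and without Rptor Lin⁻ + M-CSF replicate 2 (0.0713), Rptor Lin⁻ + M-CSF replicate 4 (0.0759), WT Lin⁻ + M-CSF replicate 2 (0.0606) or WT Lin⁻ + M-CSF replicate 4 (0.0606). The largest rises were those of Atp6v0d2, a subunit of the vacuolar proton pump, at 3.27 ± 0.15, the niacin receptor Hcar2 at 2.94 ± 0.25, the chemokine Ccl22 at 2.89 ± 0.17 and the aminopeptidase Anpep at 2.39 ± 0.15.

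The other genes of largest rise in Lin⁻ + M-CSF cells were Fabp4 (2.07), Tm4sf19 (1.90), Stfa1 (1.88), C4b (1.81), Prok2 (1.74) and Apol11b (1.74). The others of largest fall were Ifi204 (-4.01), Clec4a3 (-3.36), Ly6g (-3.33), Ms4a4a (-2.93) and Tlr8 (-2.77). The 20 genes of the rule had limma adjusted p of at most 0.0021. WT replicate 3 read 9.84 for Ly6g, a neutrophil marker, and the other 3 WT arrays 7.34, 7.62 and 7.18. The mean of the secondary granule and mature neutrophil genes was 10.52 on that array and 9.33, 9.37 and 8.99 on the others, and the change of this list, which was not called, went from -0.22 to 0.10 without it. In all, 2088 genes passed, 1135 higher and 953 lower in Rptor cells, and with arrays centred on their median 851 were higher and 1267 lower, and with cyclic loess 1055 and 1127. The arrays did not overlap for 2312 genes (13.9%, against 2.86% by chance), 1545 of them called. With the 8 Lin⁻ + M-CSF arrays fitted alone, which spread more than the others, 899 genes passed, of which 886 were among the 2088, and with array weights 1316 passed.

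Monocyte and macrophage genes as a list were lower in Rptor Lin⁻ + M-CSF cells, with 0 of 30 tested members higher and 22 lower (1 and 23 adjusted over the list alone). Their mean change was -1.12 (95% interval -1.27 to -0.98), and the call held with an estimated correlation (camera adjusted p = 7.57e-26, adjusted p = 0.00144 with an estimated correlation). Ms4a6c, a further member, fell by 1.77 ± 0.10. Stem and multipotent progenitor genes were higher, with 11 of 19 tested members higher and 0 lower (13 and 0 adjusted over the list alone), and this call also held (camera adjusted p = 1.42e-08, adjusted p = 0.0457 with an estimated correlation). The stem cell factor receptor Kit rose by 0.99 ± 0.10, Meis1 by 0.70 ± 0.12 and Hlf by 0.60 ± 0.10. Erythroid genes were higher, with 14 of 22 tested members higher and 0 lower (14 and 0 adjusted over the list alone) and camera adjusted p = 7.1e-10, adjusted p = 0.135 with an estimated correlation, and Car2 rose by 1.44 ± 0.18 and Hemgn by 1.56 ± 0.24. Megakaryocyte and platelet genes were higher, with 8 of 15 tested members higher and 0 lower (10 and 0 adjusted over the list alone) and camera adjusted p = 1.49e-05, adjusted p = 0.101 with an estimated correlation, and Vwf rose by 0.80 ± 0.13 and Gp5 by 0.90 ± 0.15. T and NK cell genes were higher, with 6 of 13 tested members higher and 0 lower (8 and 0 adjusted over the list alone) and camera adjusted p = 0.000251, adjusted p = 0.135 with an estimated correlation, and Cd3d rose by 1.11 ± 0.16, Cd3g by 0.92 ± 0.15 and Thy1 by 0.90 ± 0.17. Primary granule genes were higher, with 2 of 15 tested members higher and 0 lower (7 and 0 adjusted over the list alone) and camera adjusted p = 0.0094, adjusted p = 0.417 with an estimated correlation, and Prss57 rose by 0.64 ± 0.16 (0.42 without WT Lin⁻ + M-CSF replicate 3).

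Cholesterol synthesis genes were lower in Rptor Lin⁻ + M-CSF cells, with 0 of 19 tested members higher and 11 lower (0 and 15 adjusted over the list alone). Their mean change was -0.45 (95% interval -0.60 to -0.30), with camera adjusted p = 2.7e-11, adjusted p = 0.0537 with an estimated correlation, and Cyp51 fell by 1.05 ± 0.12 and Hsd17b7 fell by 0.88 ± 0.13. Interferon-stimulated genes were lower, with 1 of 26 tested members higher and 12 lower (1 and 13 adjusted over the list alone), and the call held with an estimated correlation (camera adjusted p = 3.55e-08, adjusted p = 0.0306 with an estimated correlation). Oasl2 (-0.98 ± 0.14) and Zbp1 (-1.15 ± 0.18) were among them. G2 and mitosis genes were lower, with 0 of 22 tested members higher and 10 lower (0 and 18 adjusted over the list alone) and camera adjusted p = 5.3e-10, adjusted p = 0.135 with an estimated correlation, and S phase genes had 0 of 25 tested members higher and 4 lower (0 and 7 adjusted over the list alone) and camera adjusted p = 0.000311, adjusted p = 0.271 with an estimated correlation. Aurkb fell by 0.52 ± 0.09 and Rrm1 fell by 0.48 ± 0.09. ATF4 targets were lower, with 0 of 21 tested members higher and 6 lower (2 and 8 adjusted over the list alone) and camera adjusted p = 0.00269, adjusted p = 0.135 with an estimated correlation. Asns, asparagine synthetase, fell by 0.87 ± 0.11 and Psat1, of serine synthesis, fell by 0.70 ± 0.11. The lysosome list was higher, with 7 of 31 tested members higher and 1 lower (9 and 1 adjusted over the list alone) and camera adjusted p = 0.00766, adjusted p = 0.271 with an estimated correlation, and Rragd rose by 0.86 ± 0.13. Its call was lost without Gpnmb and Atp6v0d2 (adjusted p = 0.0572) and with the stricter filter on dim genes (adjusted p = 0.14), where the mean change was 0.11 against 0.24. Cytosolic ribosomal proteins were higher, with 4 of 30 tested members higher and 1 lower (4 and 1 adjusted over the list alone) and camera adjusted p = 0.00408, adjusted p = 0.135 with an estimated correlation, and Rplp0 rose by 0.87 ± 0.11. The mean change of this list was 0.12, or 0.07 with arrays centred on their median.

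Of the remaining called lists in Lin⁻ + M-CSF cells, 4 lost the call with 1 array left out. Oxidative phosphorylation genes were lower, with 0 of 43 tested members higher and 3 lower (0 and 2 adjusted over the list alone) and camera adjusted p = 0.0141, adjusted p = 0.417 with an estimated correlation, a call lost without WT Lin⁻ + M-CSF replicate 2 (0.0571). Their mean change was -0.09, or -0.14 with arrays centred on their median. Uqcrq fell by 0.63 ± 0.10. Mast cell and basophil genes were lower, with 0 of 11 tested members higher and 4 lower (0 and 4 adjusted over the list alone) and camera adjusted p = 0.0282, adjusted p = 0.417 with an estimated correlation, a call lost on ranks (0.0711) and without Rptor Lin⁻ + M-CSF replicate 3 (0.0558), WT Lin⁻ + M-CSF replicate 1 (0.118) or WT Lin⁻ + M-CSF replicate 2 (0.0866). Their mean change was -0.24, or -0.36 with the stricter filter. Il6ra fell by 0.63 ± 0.11. NF-kB and inflammatory genes went both ways, with 3 of 23 tested members higher and 1 lower (4 and 1 adjusted over the list alone) and camera adjusted p = 0.0321, adjusted p = 0.417 with an estimated correlation, a call lost without Rptor Lin⁻ + M-CSF replicate 2 (0.119), Rptor Lin⁻ + M-CSF replicate 4 (0.0909), WT Lin⁻ + M-CSF replicate 2 (0.0866) or WT Lin⁻ + M-CSF replicate 4 (0.113). Their mean change of 0.10 was 0.03 without Rptor Lin⁻ + M-CSF replicate 2, 0.03 without WT replicate 4, 0.05 with arrays centred on their median, 0.15 without Rptor replicate 1, 0.20 without WT replicate 3 and 0.26 with the stricter filter. The chemokine genes Ccl4 and Ccl3 rose by 1.08 ± 0.15 and 0.80 ± 0.13, and Il1b fell by 2.58 ± 0.35. Eosinophil genes had 1 of 7 tested members higher and 2 lower (1 and 4 adjusted over the list alone) and camera adjusted p = 0.0321, adjusted p = 0.417 with an estimated correlation, a call lost with the stricter filter (0.14), with arrays centred on their median (0.0552) and without Rptor Lin⁻ + M-CSF replicate 2 (0.0702), Rptor Lin⁻ + M-CSF replicate 3 (0.0691), WT Lin⁻ + M-CSF replicate 2 (0.101) or WT Lin⁻ + M-CSF replicate 4 (0.107). Epx fell by 2.00 ± 0.33 and Siglecf rose by 0.56 ± 0.13. The other 16 lists had adjusted p from 0.0564 to 0.956. In Lin⁻ + M-CSF cells 17 lists were called, and up to 19 in other splits of these arrays that keep part of the genotype difference. Splits that mix the genotypes evenly called up to 8.

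**Figure D2:**
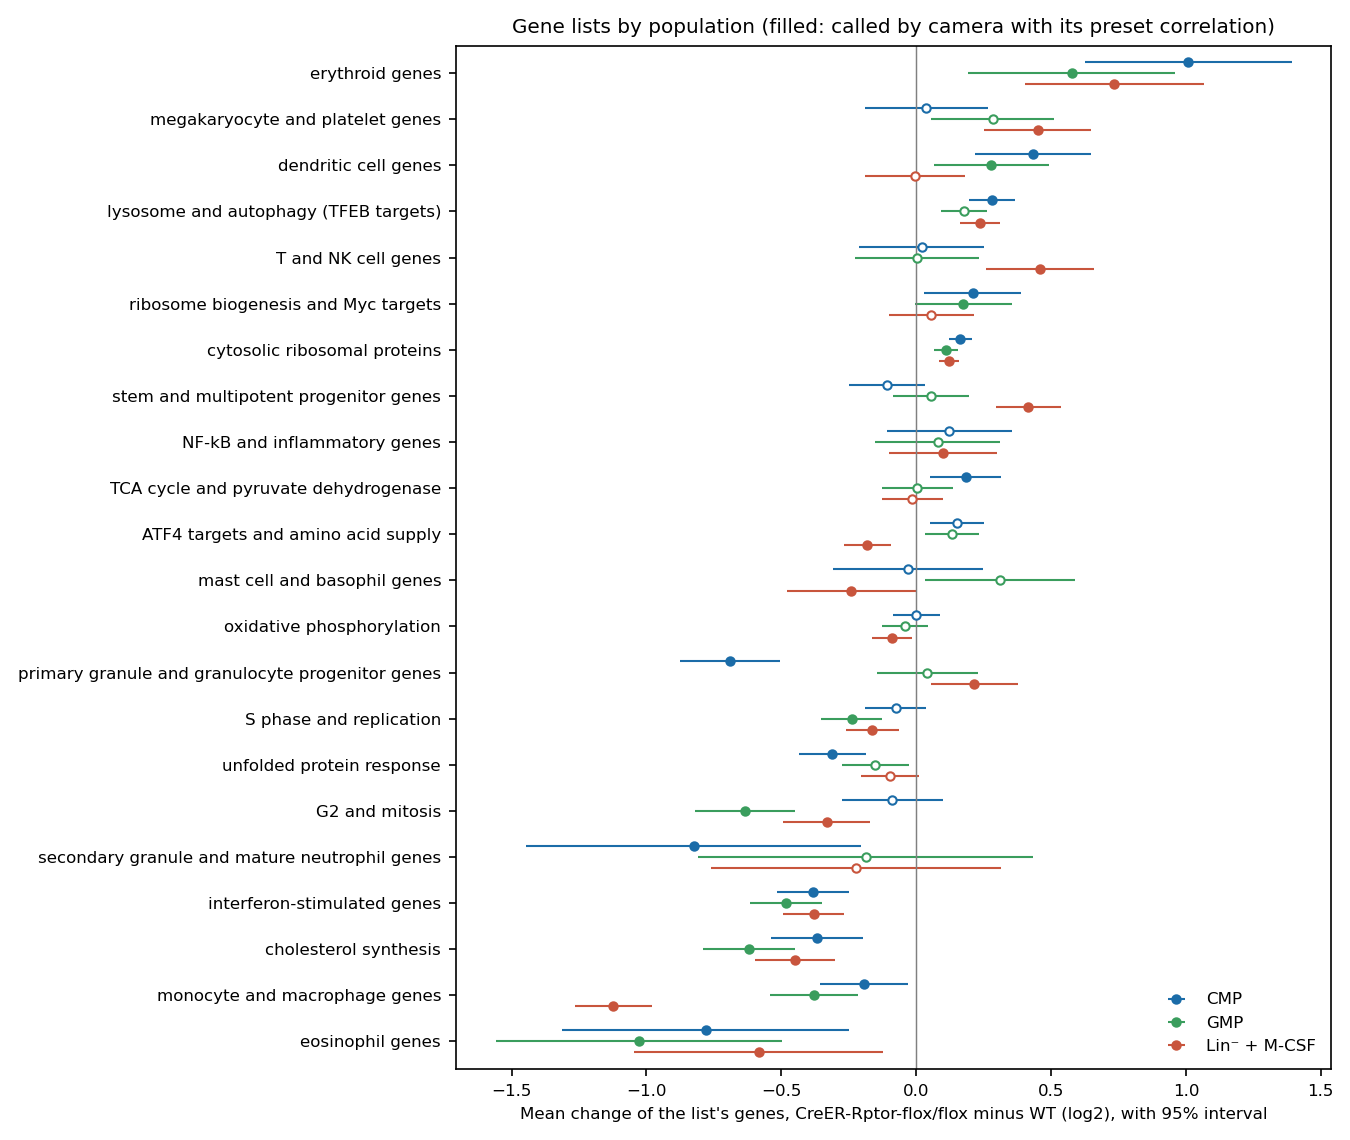
Mean log2 change between genotypes (horizontal axis) of the genes of 22 fixed lists that were called in at least 1 population, with the 95% interval over arrays; colours mark populations and filled points mark lists called by camera with its preset correlation. Cholesterol synthesis and interferon-stimulated genes lie below 0 and erythroid genes above 0 in all 3 populations, and monocyte and macrophage genes lie at -1.12 in Lin⁻ + M-CSF cells.

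The genotype changes of the 3 populations ran in the same direction for many genes. Across 16638 genes, which are not independent replicates, the changes correlated at r = 0.575 (Spearman rho = 0.394) between CMPs and GMPs, 0.278 (rho = 0.242) between CMPs and Lin⁻ + M-CSF cells, and 0.403 (rho = 0.318) between GMPs and Lin⁻ + M-CSF cells. These comparisons share no arrays, and the labels do not say whether they share animals. CMPs and GMPs shared 298 genes called higher and 498 called lower, where independent lists of these sizes would share 43.7 and 68.2. Genes called in the same direction in all 3 populations numbered 129 higher and 184 lower, where independent lists would give 2.98 and 3.90. The fit uses 1 spread per gene for all 3 comparisons, so a gene of low spread is called more easily in each. The numbers for independent lists do not take this into account. Csf1r, Irf8, Klf4, Fn1, Ms4a4c, Itga1 and Abca9 were lower in all 3, and Anpep, Fabp4, C4b, Mt2 and Cd33 were higher. Of 7 tested genes of the interferon-inducible Ifi200 family, which lie next to each other, Ifi209, Ifi204 and Mndal were lower in all 3.

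Of the other genes fixed in advance, Myc was higher by 0.49 ± 0.14 in GMPs (limma adjusted p = 0.0309) and 0.61 ± 0.13 in Lin⁻ + M-CSF cells (adjusted p = 0.00229), and differed by 0.09 ± 0.14 in CMPs without passing. Gfi1, a granulocyte transcription factor, was higher by 0.69 ± 0.20 in GMPs (adjusted p = 0.0309) and 0.57 ± 0.18 in Lin⁻ + M-CSF cells (adjusted p = 0.0378), and differed by -0.20 ± 0.20 in CMPs without passing. Hexokinase 2 (Hk2) fell by 0.61 ± 0.13 in CMPs and fell by 0.41 ± 0.13 in GMPs (adjusted p = 0.0406), and differed by -0.14 in Lin⁻ + M-CSF cells. The glucose transporter gene Slc2a1 was higher by 0.57 ± 0.14 in GMPs and differed by -0.14 in CMPs and -0.24 in Lin⁻ + M-CSF cells. Srebf2 fell by 0.52 ± 0.11 in GMPs and differed by -0.12 in Lin⁻ + M-CSF cells. Srebf1 (0.16, -0.08 and -0.25) and Cebpa (-0.24, 0.36 and 0.28) did not pass in any of the 3 populations. Spi1 differed by -0.21 in GMPs and -0.19 in Lin⁻ + M-CSF cells, and Cd36 by 0.74 in CMPs and 0.11 in GMPs, without passing.

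Several of these calls depended on single arrays. In GMPs the call of Myc was lost without Rptor GMP replicate 1 (0.0952), Rptor GMP replicate 3 (0.0915), WT GMP replicate 1 (0.0837) or WT GMP replicate 2 (0.134), that of Gfi1 without Rptor GMP replicate 1 (0.0929), Rptor GMP replicate 2 (0.177), WT GMP replicate 1 (0.117) or WT GMP replicate 2 (0.17), and that of Hk2 without Rptor GMP replicate 1 (0.0708), Rptor GMP replicate 2 (0.15), Rptor GMP replicate 3 (0.0705), WT GMP replicate 1 (0.0657), WT GMP replicate 2 (0.2) or WT GMP replicate 3 (0.0595). In Lin⁻ + M-CSF cells the call of Gfi1 was lost without Rptor Lin⁻ + M-CSF replicate 1 (0.122), Rptor Lin⁻ + M-CSF replicate 2 (0.0762), Rptor Lin⁻ + M-CSF replicate 3 (0.0517), WT Lin⁻ + M-CSF replicate 1 (0.0621), WT Lin⁻ + M-CSF replicate 3 (0.12) or WT Lin⁻ + M-CSF replicate 4 (0.0876). Other settings ended calls too. The replicate number as a block ended those of Gfi1 in GMPs (0.0544) and Lin⁻ + M-CSF cells (0.0633) and of Hk2 in GMPs (0.0717). An ordinary linear model ended those of Myc (0.0527), Gfi1 (0.075) and Hk2 (0.0516) in GMPs and of Gfi1 in Lin⁻ + M-CSF cells (0.083). That of Gfi1 in Lin⁻ + M-CSF cells was also lost with array weights (0.0999) and with these arrays fitted alone (0.081). Hk2 in GMPs lost it with arrays centred on their median (0.0513), cyclic loess (0.0566) and repeated quantile normalization (0.0751). With the mean of its probe sets Slc2a1 differed by 0.33 in GMPs without passing (0.0792).

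WT GMPs were set against WT CMPs to show how the markers behaved between the populations. Erythroid and platelet genes were lower in GMPs. Car1 fell by 4.42 ± 0.40, Ces2g fell by 4.29 ± 0.27, the blood group gene Ermap fell by 4.03 ± 0.34, Car2 fell by 3.87 ± 0.21 and platelet factor 4 (Pf4) fell by 3.30 ± 0.22. Aqp1 (-3.56), Rhag (-3.42), Kel (-3.30), Mfsd2b (-3.09) and Ctla2a (-2.96) were the others of largest fall. The eosinophil granule genes Epx and Prg3 were higher by 2.98 ± 0.39 and 2.52 ± 0.30, and Klf4 by 1.91 ± 0.15. H4f16 (1.97, or 0.95 with the mean of its probe sets), Rny3 (1.89), Rpph1 (1.81), Mgl2 (1.81), Ear6 (1.80) and Gpr141 (1.79) were others of largest rise. Csf1r was higher in GMPs by 0.64 ± 0.11, Spi1 by 0.61 ± 0.12 and Rptor by 0.65 ± 0.13. Gfi1 was higher by 0.64 ± 0.20 (adjusted p = 0.0471), a call lost without a filter on dim genes (0.0589), with an ordinary linear model (0.101) and without WT CMP replicate 1 (0.154), WT CMP replicate 2 (0.194), WT GMP replicate 1 (0.0737) or WT GMP replicate 3 (0.306). In all, 1831 genes passed, 1107 higher and 724 lower in GMPs. The split was 1019 and 875 with cyclic loess, 1098 and 797 with repeated quantile normalization, 2092 and 1903 with array weights and 1308 and 649 with arrays centred on their median. The arrays did not overlap for 5862 genes (35.2%, against 10% by chance), 1820 of them called. The count was 803 without WT GMP replicate 3, 1011 without WT CMP replicate 2, 1139 without WT CMP replicate 1, 1136 without WT GMP replicate 1, and 3995 with array weights.

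As lists, erythroid genes were lower in WT GMPs, with 0 of 22 tested members higher and 18 lower (0 and 20 adjusted over the list alone) and camera adjusted p = 5.42e-31, adjusted p = 0.0201 with an estimated correlation. Megakaryocyte and platelet genes had 0 of 15 tested members higher and 8 lower (0 and 9 adjusted over the list alone) and camera adjusted p = 1.01e-08, adjusted p = 0.0416 with an estimated correlation, and Vwf fell by 1.06 ± 0.15. Stem and multipotent progenitor genes had 0 of 19 tested members higher and 7 lower (0 and 12 adjusted over the list alone) and camera adjusted p = 3.39e-08, adjusted p = 0.0488 with an estimated correlation, and Flt3 fell by 2.03 ± 0.18. These 3 calls held with an estimated correlation. Lysosome and autophagy genes were higher, with 11 of 31 tested members higher and 0 lower (14 and 0 adjusted over the list alone) and camera adjusted p = 1.59e-06, adjusted p = 0.0668 with an estimated correlation, and Neu1 rose by 0.97 ± 0.15. Monocyte and macrophage genes were higher, with 12 of 30 tested members higher and 0 lower (14 and 0 adjusted over the list alone) and camera adjusted p = 5.9e-05, adjusted p = 0.188 with an estimated correlation, and Fn1 rose by 1.59 ± 0.17. Primary granule genes were higher, with 4 of 15 tested members higher and 0 lower (10 and 0 adjusted over the list alone) and camera adjusted p = 2.8e-06, adjusted p = 0.212 with an estimated correlation, and eosinophil genes, with 4 of 7 tested members higher and 0 lower (5 and 0 adjusted over the list alone) and camera adjusted p = 6.23e-06, adjusted p = 0.16 with an estimated correlation.

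A further 4 lists were called between WT GMPs and WT CMPs and lost the call without single arrays. Ribosome biogenesis and Myc targets had 0 of 34 tested members higher and 8 lower (2 and 10 adjusted over the list alone) and camera adjusted p = 0.0268, adjusted p = 0.824 with an estimated correlation, a call lost on ranks (0.051) and without WT CMP replicate 1 (0.0538) or WT CMP replicate 3 (0.0526). Interferon-stimulated genes had 0 of 26 tested members higher and 1 lower (0 and 0 adjusted over the list alone) and camera adjusted p = 0.0271, adjusted p = 0.407 with an estimated correlation, a call lost without WT CMP replicate 3 (0.12) or WT GMP replicate 1 (0.0567). The components of the mTOR pathway had 3 of 26 tested members higher and 1 lower (5 and 1 adjusted over the list alone) and camera adjusted p = 0.0271, adjusted p = 0.407 with an estimated correlation, a call lost with the stricter filter (0.0591), array weights (0.0627), cyclic loess (0.077) or repeated quantile normalization (0.108) and without WT CMP replicate 2 (0.123) or WT GMP replicate 2 (0.0704). Dendritic cell genes had 0 of 14 tested members higher and 2 lower (0 and 4 adjusted over the list alone) and camera adjusted p = 0.0293, adjusted p = 0.475 with an estimated correlation, a call lost with the stricter filter (0.114) and without WT CMP replicate 2 (0.113) or WT GMP replicate 1 (0.101). The other 22 lists had adjusted p from 0.0619 to 0.838.

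Differences between the genotype changes of 2 populations were tested as interactions. The changes of Msr1 (-4.74 ± 0.28) and Vcan (-4.68 ± 0.17) were lower in Lin⁻ + M-CSF cells than in CMPs, and those of the granule genes Ltf (3.39 ± 0.36) and Camp (3.32 ± 0.29) were higher. Against GMPs, the change of Irf8 was higher in Lin⁻ + M-CSF cells (2.21 ± 0.24) and that of Cd36 lower (-2.17 ± 0.50). Cebpe changed more in CMPs than in GMPs (1.72 ± 0.25), and so did Rec8 (-2.33 ± 0.31). For GMPs against CMPs 416 genes passed, 111 with a higher and 305 with a lower change in GMPs, and with arrays centred on their median 166 and 255. For Lin⁻ + M-CSF cells against CMPs 1292 passed, 718 higher and 574 lower, and with cyclic loess 679 and 688. For Lin⁻ + M-CSF cells against GMPs 793 passed, 488 higher and 305 lower, and with arrays centred on their median 333 and 403. The first count was 228 without Rptor CMP replicate 2, 647 without Rptor CMP replicate 3, 265 without WT CMP replicate 3, 276 without WT GMP replicate 1, 245 without WT GMP replicate 2, 654 with these populations fitted alone and 1980 with array weights. The last was 488 without WT GMP replicate 2 and 1330 with array weights.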

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

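The splits below and the test of the neighbours of the Ifi200 genes were set down before their results were seen. The comparison of late and progenitor erythroid genes was also set down before, but its repeat on genes above the median level was chosen afterwards. The comparison of erythroid with megakaryocyte genes and the use of the interferon-stimulated list were chosen after those lists had been seen.

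Counts were set against other splits of the same arrays. For Lin⁻ + M-CSF cells, 1 of 35 splits, the real one, gave as many called genes (2088, with 72 as the highest of the others). That share is under 0.05 and argues against a chance split if the arrays are independent samples, which the labels do not say. The other splits mix the genotypes, which widens the spread within groups, so their counts do not show what arrays without a genotype difference would give. CMPs, GMPs and WT GMPs against CMPs have 10 splits each, too few for a share under 0.05. In each, 1 split, the real one, gave the most called genes: 1905 in CMPs (highest other 1), 1980 in GMPs (highest other 97) and 1831 between WT populations (highest other 1). The list counts stand less apart. As many lists were called in 4 of 35 splits in Lin⁻ + M-CSF cells (17, highest other 19), so chance cannot be excluded for that count. They were called in 5 of 10 in CMPs (13, highest other 15), 1 of 10 in GMPs (10, highest other 8) and 2 of 10 between WT populations (11, highest other 12).

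For the interactions, 100 relabellings of genotype within the 2 populations were drawn. They do not hold the changes shared by both populations fixed, so their shares decide nothing about chance, whatever share was set down beforehand. As many genes were called in 11 for GMPs against CMPs (416, highest other 3155), in 5 for Lin⁻ + M-CSF cells against CMPs (1292, highest other 2763) and in 3 for Lin⁻ + M-CSF cells against GMPs (793, highest other 1332). The 3155 for GMPs against CMPs, several times the real count, came with the genotypes fully exchanged in 1 population. All 10, 4 and 2 of the other splits as large in the 3 comparisons had the genotypes mostly exchanged in 1 population, which adds the changes shared by both populations instead of subtracting them. Among the other relabellings the highest counts were 368, 861 and 668. List counts as large came in 44 of 100 (9 lists, highest other 15), 31 of 100 (12 lists, highest other 18) and 38 of 100 (8 lists, highest other 17), with the same limit.

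Genotype changes that differed between GMPs and CMPs by the interaction test numbered 416. Changes higher in GMPs were those of Svep1 (by 2.36, or 1.22 with the mean of its probe sets; 1.25 in CMPs and 3.60 in GMPs), Lipg (2.26), Slco4c1 (2.12; -1.14 and 0.98), Cebpe (1.72; -1.76 and -0.04) and Gpc3 (1.67). Lower in GMPs were those of Plxdc1 (-3.66; 1.23 and -2.44), Rec8 (-2.33), Ano1 (-2.31), Pkd1l3 (-2.22), Nxpe4 (-2.22), Klf4 (-1.49) and Csf1r (-0.69), a call lost with the replicate number as a block (adjusted p = 0.0581), with repeated quantile normalization (0.0537) and without Rptor CMP replicate 1 (0.0539). By list mean, the difference was 0.73 for primary granule, 0.64 for secondary granule, 0.34 for mast cell, 0.16 for unfolded protein response and 0.14 for glycolysis genes. It was -0.55 for G2 and mitosis, -0.43 for erythroid, -0.25 for cholesterol synthesis and -0.16 for S phase genes. With an estimated correlation the adjusted p of these 9 lists were 0.0909 to 0.504. The difference of erythroid genes was -0.28 without Rptor CMP replicate 2, that of mast cell genes 0.54 with the stricter filter and that of S phase genes -0.11 with arrays centred on their median and -0.10 with cyclic loess. The number of called lists was 5 without Rptor GMP replicate 3. With the preset correlation the call of mast cell genes was lost without Rptor CMP replicate 1 (0.073), Rptor CMP replicate 2 (0.0514) or Rptor GMP replicate 3 (0.0563), that of unfolded protein response genes without Rptor GMP replicate 1 (0.056), Rptor GMP replicate 3 (0.0789), WT CMP replicate 3 (0.094) or WT GMP replicate 3 (0.0831), that of glycolysis genes without Rptor CMP replicate 3 (0.0546), Rptor GMP replicate 3 (0.0819), WT CMP replicate 1 (0.0531), WT CMP replicate 3 (0.0967) or WT GMP replicate 3 (0.058), that of cholesterol synthesis genes without Rptor GMP replicate 3 (0.0588) or WT CMP replicate 2 (0.0681) and that of S phase genes without Rptor CMP replicate 2 (0.0531). Other settings, each with its adjusted p, ended the calls of S phase genes (stricter filter 0.0859, cyclic loess 0.182, repeated quantile normalization 0.0723), of cholesterol synthesis genes (stricter filter 0.0559, cyclic loess 0.0515) and of glycolysis genes (populations fitted alone 0.0721).

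Between Lin⁻ + M-CSF cells and CMPs 1292 changes differed. Higher in Lin⁻ + M-CSF cells were those of Ltf (by 3.39; -3.77 in CMPs and -0.38 in Lin⁻ + M-CSF cells), Camp (3.32), Ccl22 (2.92), Atp6v0d2 (2.79), Hcar2 (2.74) and Irf8 (1.33). Lower were those of Msr1 (-4.74; 0.18 and -4.56), Vcan (-4.68), Clec4a1 (-4.56), Clec4a3 (-4.01), Gpnmb (-3.88; 4.33 and 0.45), Cd36 (-2.80) and Klf4 (-0.99). By list mean, primary granule genes differed by 0.90, secondary granule by 0.60, stem and multipotent by 0.52, T and NK cell by 0.44, megakaryocyte by 0.41 and unfolded protein response genes by 0.21. Monocyte and macrophage genes differed by -0.93, dendritic cell by -0.44, ATF4 targets by -0.33, G2 and mitosis by -0.24, TCA cycle by -0.20 and ribosome biogenesis by -0.15. Without WT Lin⁻ + M-CSF replicate 3, whose secondary granule mean stood at 10.52 against 9.33, 9.37 and 8.99 on the other WT arrays, the secondary granule difference was 0.93. Without WT Lin⁻ + M-CSF replicate 1 the ribosome biogenesis difference was -0.08. With an estimated correlation the adjusted p were 0.063 to 0.71. With the preset correlation the call of T and NK cell genes was lost without WT CMP replicate 2 (0.0502), that of unfolded protein response genes without WT CMP replicate 3 (0.0598) or WT Lin⁻ + M-CSF replicate 3 (0.0545), that of TCA cycle genes without Rptor CMP replicate 2 (0.11), Rptor Lin⁻ + M-CSF replicate 4 (0.13), WT CMP replicate 2 (0.0837), WT Lin⁻ + M-CSF replicate 1 (0.105) or WT Lin⁻ + M-CSF replicate 2 (0.0647) and that of ribosome biogenesis genes without Rptor CMP replicate 2 (0.0568), WT CMP replicate 2 (0.0675), WT Lin⁻ + M-CSF replicate 1 (0.264) or WT Lin⁻ + M-CSF replicate 3 (0.0548). Other settings, each with its adjusted p, ended the calls of TCA cycle genes (stricter filter 0.0526, array weights 0.0869, mean of probe sets 0.0503, repeated quantile normalization 0.0699) and of ribosome biogenesis genes (array weights 0.0709).

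Between Lin⁻ + M-CSF cells and GMPs 793 changes differed. Higher in Lin⁻ + M-CSF cells were those of Hspa1a (by 3.16; -3.15 in GMPs and 0.00 in Lin⁻ + M-CSF cells), Ltf (3.15), Atp6v0d2 (3.11), Ifi209 (2.83), Mgl2 (2.77; -2.09 and 0.68), Irf8 (2.21) and Csf1r (0.80). The call of Hspa1a was lost with array weights (0.0848), with a trended and robust eBayes (0.0907), with an ordinary linear model (0.106) and without Rptor GMP replicate 1 (0.0614), Rptor GMP replicate 2 (0.0783), Rptor GMP replicate 3 (0.0502), Rptor Lin⁻ + M-CSF replicate 1 (0.053), WT GMP replicate 2 (0.107), WT GMP replicate 3 (0.0597) or WT Lin⁻ + M-CSF replicate 4 (0.0532). With the mean of its probe sets the difference of Slc2a1 did not pass (0.172), nor did that of Cd36 with an ordinary linear model (0.0618). Lower were those of Vcan (-4.91), Msr1 (-4.67), Clec4a1 (-4.35), Gpnmb (-3.71), Ms4a4a (-3.45; 0.52 and -2.93), Cd36 (-2.17) and Slc2a1 (-0.81). By list mean, T and NK cell genes differed by 0.45, stem and multipotent by 0.36 and G2 and mitosis by 0.30. Monocyte and macrophage genes differed by -0.74, mast cell by -0.55, ATF4 targets by -0.32, dendritic cell by -0.28 and ribosome biogenesis by -0.12. The ribosome biogenesis difference was -0.04 without WT Lin⁻ + M-CSF replicate 1, -0.18 without WT Lin⁻ + M-CSF replicate 4 and -0.20 with arrays centred on their median or with cyclic loess. With the stricter filter the monocyte and macrophage difference was -0.49 and that of dendritic cell genes -0.44. With an estimated correlation the adjusted p were 0.172 to 0.936. With the preset correlation the call of dendritic cell genes was lost without Rptor GMP replicate 2 (0.076), Rptor GMP replicate 3 (0.0578), Rptor Lin⁻ + M-CSF replicate 2 (0.0694), Rptor Lin⁻ + M-CSF replicate 4 (0.147), WT GMP replicate 1 (0.0981), WT Lin⁻ + M-CSF replicate 1 (0.0583), WT Lin⁻ + M-CSF replicate 2 (0.0745) or WT Lin⁻ + M-CSF replicate 4 (0.118), and that of ribosome biogenesis genes without Rptor GMP replicate 1 (0.111), Rptor GMP replicate 3 (0.244), Rptor Lin⁻ + M-CSF replicate 3 (0.148), Rptor Lin⁻ + M-CSF replicate 4 (0.1), WT GMP replicate 1 (0.0763), WT GMP replicate 3 (0.0956), WT Lin⁻ + M-CSF replicate 1 (0.512) or WT Lin⁻ + M-CSF replicate 3 (0.158). Other settings, each with its adjusted p, ended the calls of dendritic cell genes (array weights 0.0519, arrays centred on their median 0.066, populations fitted alone 0.0522, repeated quantile normalization 0.0655), of ribosome biogenesis genes (array weights 0.101, no filter 0.0656, populations fitted alone 0.0522, replicate number as a block 0.0551), of G2 and mitosis genes (array weights 0.0624) and of stem and multipotent genes (stricter filter 0.0523).

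Single arrays stood far from the rest of their group of 4 in 5 of 76 group values tested, where chance gives about 1 in 20. The gap divided by the range was 0.928 for Ccl22 (WT Lin⁻ + M-CSF replicate 1 at 5.85), 0.833 for Prok2 (WT replicate 3 at 6.27), 0.834 for Ly6g, a neutrophil marker (WT replicate 3 at 9.84), 0.848 for Tlr8 (Rptor replicate 1 at 4.52) and 0.906 for the interquartile range of Rptor replicate 3 (3.23). Of 11555 tested probe sets with several or no gene symbols, 171 were called in CMPs, 189 in GMPs and 223 in Lin⁻ + M-CSF cells.

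Erythroid genes were higher in Rptor CMPs (adjusted p = 0.102 with an estimated correlation, which ends the call), where CMPs can hold cells primed for either path. A CMP gate with fewer granulocyte-monocyte primed cells, all other classes raised alike, was taken to raise erythroid and megakaryocyte genes by about as much. The erythroid list rose by 0.97 more than the megakaryocyte list (95% interval 0.55 to 1.39), which argues against equal rises. It does not decide about the gate, because the lists need not respond alike. Between WT GMPs and WT CMPs their mean changes were -1.87 and -0.69. The mean change of 9 late erythroid genes less that of 10 erythroid progenitor genes was -0.42 (95% interval -0.63 to -0.20), the outcome set down against carry-over of late erythroid cells, but 6 of the 9, Epb42 (0.11) and Bpgm (-0.04) among them, lay below the median level of tested genes in WT CMPs (log2 6.30), and dim genes exclude nothing. Over the other 3, Kel (1.59), Cldn13 (0.94, not called) and Slc4a1 (0.85), the difference from progenitor genes was 0.12 (-0.29 to 0.54), and Sptb, at 5.95 in WT, rose by 1.26. Carry-over of late erythroid cells, fewer granulocyte-monocyte primed cells or a higher share of erythroid progenitors in the gate, and a change within cells all stay open. The genotype remains an untested candidate explanation.

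Interferon-inducible genes were lower in Rptor cells of all 3 populations, with changes of Ifi209 of -3.99, -4.26 and -1.43 log2 units in CMPs, GMPs and Lin⁻ + M-CSF cells. A strain variant at the Ifi200 locus that acts on the Ifi200 genes alone is argued against as the whole source. The interferon-stimulated list, which holds no Ifi200 gene, had a mean change of -0.38 in the population where it moved least. Its intervals lay below 0 in all 3, though its camera call in CMPs was lost with an estimated correlation (adjusted p = 0.102). A variant there that also changes other interferon-inducible genes through the Ifi200 genes is not covered, as that was not tested. For the Ifi200 genes themselves a local variant cannot be told apart from the genotype: 3 of 7 tested family members (Ifi209, Ifi204 and Mndal) were called in all 3 populations. Of 50 neighbouring genes outside the family, taken by gene order in GRCm38.p6, 2 (Kmo and Smyd3) were called in all 3, with 0.93 expected (one-sided Fisher exact p = 0.239), and the number is too small to decide. A lower interferon tone with the genotype stays open as a hypothesis.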

How the results depend on the processing

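All settings here were planned before the data were examined. Of 491 results for named genes, 8472 of 9330 values under other settings kept direction and side of the threshold, 837 lost the call, 9 gained it and 12 reversed, all 12 of genes not called. Of 80 called lists, 1504 of 1688 values kept the call and 184 lost it, with none reversed. With array weights Srebf1 (0.056) and Rictor (-0.028) reversed in GMPs. With single arrays left out, reversals gave ranges of -0.31 to 0.047 for Slc2a1 and -0.063 to 0.23 for Myc in CMPs, and in GMPs of -0.042 to 0.075 for Mtor, -0.12 to 0.13 for Rictor, -0.035 to 0.22 for Cd36 and -0.16 to 0.017 for Srebf1. The cause was not tested. With arrays fitted alone 899 genes were called in Lin⁻ + M-CSF cells and 654 for GMPs against CMPs. Array weights gave 3048 in CMPs, 5328 in GMPs, 1316 in Lin⁻ + M-CSF cells, 3995 between WT populations, 1980 for GMPs against CMPs and 1330 for Lin⁻ + M-CSF cells against GMPs, with 5 lists in the last. The arrays of Lin⁻ + M-CSF cells spread more, which both settings take into account. Array weights also differed within groups. Rptor GMP replicate 1 had a weight of 4.70 against 0.82 and 0.52 for the other Rptor GMP arrays. WT GMP replicate 1 had 2.84 against 1.26 and 1.03. The weighted counts in GMPs therefore lean on single arrays. Fitted alone, CMPs gave 2113 genes and GMPs 2350. A fold change of at least 1.5 left 1135, 1017 and 714 genes in the 3 populations and 837 between WT populations. No filter gave 14 lists for GMPs against CMPs. Camera with an estimated correlation called 0, 1 and 3 lists in the 3 populations, 3 between WT populations and 0, 0 and 0 in the interactions. Over genes above the 50th percentile the correlations with Lin⁻ + M-CSF changes were 0.321 for CMPs and 0.476 for GMPs, a set without the dimmer genes.

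Without each array in turn, called genes ranged from 1229 to 1767 in CMPs, 1183 to 2086 in GMPs, 1634 to 1910 in Lin⁻ + M-CSF cells and 803 to 1551 between WT populations, and lists from 12 to 15, 9 to 12, 13 to 20 and 9 to 12. For GMPs against CMPs the ranges were 228 to 647 genes and 5 to 11 lists (5 without Rptor GMP replicate 3), for Lin⁻ + M-CSF cells against CMPs 933 to 1365 and 10 to 15, and against GMPs 488 to 842 and 6 to 9. Correlations ranged from 0.522 to 0.61 for CMPs and GMPs, 0.257 to 0.285 for CMPs and Lin⁻ + M-CSF cells and 0.378 to 0.414 for GMPs and Lin⁻ + M-CSF cells. Each of these fits has 1 array fewer, yet the counts differed with the array left out. Gene counts of 2086 in GMPs and 647 for GMPs against CMPs lay above those of the full fit (1980 and 416). So did 1365 for Lin⁻ + M-CSF cells against CMPs (1292 in the full fit) and 842 against GMPs (793). Named genes kept their call without each array in 86 of 109 cases in CMPs, 76 of 111 in GMPs, 92 of 118 in Lin⁻ + M-CSF cells and 50 of 89 between WT populations. The labels do not say whether equal replicate numbers mark a shared animal or day. Arrays of the 2 genotypes with the same number had deviations correlated at -0.344 to 0.119, and 1 of 10 pairs matched each other best. For CMP and GMP arrays with the same number the correlations were 0.068, 0.005 and 0.087 in WT, where 1 of 3 pairs matched each other best, and 0.185, 0.048 and 0.171 in Rptor cells, where 3 of 3 did. As not every pair lay above 0.1, the numbers were not taken to pair the arrays, but these positive values are a hint from the data that CMP and GMP arrays may share something by number, which bears on WT GMPs against WT CMPs and on the interaction of these populations. With the replicate number as a block 1602, 1529 and 1571 genes were called in CMPs, GMPs and Lin⁻ + M-CSF cells, 2178 between WT populations (in a fit of the CMP and GMP arrays) and 309, 1065 and 572 in the interactions. It ended 40 of the calls of named genes and 2 of those of lists. Under the scalings tried, the median change of all genes lay farthest from 0 at -0.067. Dim genes limit the data, since signal over background was not analysed here.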

Other observations

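The tests of the labels, of the lysosome list without its leading genes and of neighbouring genes were set down before their results were seen. The interval of the reduced lysosome list was chosen after the values had been seen.

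Further genes higher in all 3 populations, chosen after their values were seen, included Gadd45g, a stress-response gene (1.23, 1.72 and 1.42 log2 units in CMPs, GMPs and Lin⁻ + M-CSF cells), Xrcc5, which encodes the DNA repair protein Ku80 (1.62, 1.76 and 1.29), and the carboxylesterase gene Ces2g (1.96, 2.31 and 1.37). Among those lower in all 3 were Ly86, an accessory protein of Toll-like receptor signalling (-1.77, -2.36 and -1.12), and Nrp1 (-1.36, -2.39 and -1.44). Hspa1a ran in parallel on WT arrays with the same number in CMPs (4.81, 8.27 and 6.22) and GMPs (5.32, 8.60 and 6.81), which was noticed in the data.

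The Rptor probe set differed little between genotypes, as given in the report. Single arrays with the wrong genotype label, among arrays otherwise labelled rightly, are argued against. In the mean of the cholesterol synthesis genes, 10 of 10 Rptor arrays lay below every WT array of their population. The same held for 10 of 10 in Csf1r. Both were called as different between these same labels, so some separation is built in. An exchange of all labels of a population would leave its arrays as far apart and was not tested. Probes outside the floxed part, and cells that kept an intact allele, stay open, as no value here bears on either. The changes between genotypes come from animals whose Cre induction the labels do not describe, and effects of CreER or of its induction were not tested.

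A hypothesis was that 2 genes, Gpnmb and Atp6v0d2, alone carry the rise of the lysosome and autophagy list. Without them, 29 genes were left and the list lost its call in CMPs (adjusted p = 0.0912) and Lin⁻ + M-CSF cells (0.0572). The mean change went from 0.28 (95% interval 0.20 to 0.37) to 0.14 (0.05 to 0.22) in CMPs, and from 0.24 (0.16 to 0.31) to 0.12 (0.05 to 0.20) in Lin⁻ + M-CSF cells. The loss of the call was the outcome set down beforehand for the hypothesis, while these intervals, looked at afterwards, lay above 0. In GMPs, where the list was not called, the mean went from 0.18 (0.09 to 0.26) to 0.04 (-0.05 to 0.12). With an estimated correlation, under which the full list was not called either, the adjusted p without the 2 genes were 0.53 in CMPs and 0.417 in Lin⁻ + M-CSF cells. Whether the 2 genes alone carry the shift stays open, and the rise of the list is not shown without them.

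Another hypothesis was that variants in DNA flanking the Rptor or the Gt(ROSA)26Sor locus may add to the genes called alike in all 3 populations. Of 200 tested genes, the nearest 50 on either side of each locus by gene order in GRCm38.p6, 4 were called in all 3 (St6galnac2, Usp36 and Gaa beside Rptor and Bhlhe40 beside the other), with 3.77 expected (one-sided Fisher exact p = 0.522). The numbers are too small to decide, and whether the Cre sits at that locus is not stated in the labels.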
